A study of Danio rerio with 6 samples.

How the data were processed

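Bulk RNA sequencing libraries of sorted dsRed-positive cells from zebrafish skeletal tissue were analysed from the files the authors deposited. Per the labels, tissue was dissociated with trypsin and collagenase, live single cells positive for dsRed were sorted, 5000 cells from each of 2 fish were combined per replicate, and libraries were made with an ultra-low input method. There were 3 WT and 3 clcn7-/- replicates, which the labels call biological replicates, and no other groups. Per the submitters' processing notes, Trim Galore, STAR 2.7.0a, HTSeq 0.9.1, DESeq2 and the GRCz11 assembly were used. The gene annotation, the strand setting and the settings of each tool are not given in the sources used here.

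The deposited values used are whole read counts per gene, 1 file per library, over 36351 gene rows. The 5 rows that name no gene (such as reads outside any gene or in several genes) held between 20.1% and 23.0% of all rows' counts and were left out of library sizes and tests. The authors also deposited a table with a log2 value per gene and library, a log2 fold change and an adjusted p-value from DESeq2, per the file headers and the processing notes. Its values per library equal log2 of a sum, the count divided by a size factor plus 4, and after undoing this 99% of values over 21939 genes lay within 0.01 reads of the deposited count. All 29 mitochondrial gene rows are 0 in the count files, and 19 of them have values in the authors' deposited table. Gene symbols were taken from the count files, in which 216 symbols name more than 1 row.

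Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and a quasi-likelihood fit with genotype as the only term was tested with glmQLFTest. p-values were adjusted by the Benjamini-Hochberg method over the 20438 genes tested, and a gene was called at adjusted p under 0.05. CPM values are those of edgeR's cpm function with TMM-scaled library sizes. The SE of a log2 fold change is its size divided by the square root of the F statistic. In the text, values after ± are SE for log2 fold changes and SD over 3 libraries for CPM. The libraries held 22739782 to 26951306 counts over genes, and the common biological coefficient of variation was 35.3%. Counts were simulated for the 20438 genes with 200 of them changed. The same steps called 13 of 95 genes changed 2-fold, 50 of 92 changed 4-fold and 4 of 19700 unchanged genes. The Benjamini-Hochberg cut-off depends on how many genes change. In the data 3012 genes were called, so these shares do not give the power of the real comparison. A simulated list of 30 genes moved 1.5-fold was called, and 1 of 100 unchanged lists had p under 0.05, in a simulation where genes vary independently.

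The gene lists, the rule for naming genes, the tests and the alternatives were fixed before the data were examined. The 33 lists (20 of pathways and 13 of cell type markers) were tested with camera at a preset inter-gene correlation of 0.01, repeated with an estimated correlation, and with fry, for the 32 lists with at least 5 tested genes. The list of secreted ligands matches by prefix; receptors and unrelated genes that share a prefix were left out, which was decided after the files were seen. The rule names clcn7 and ostm1, 7 osteoclast genes, and the 8 highest and 8 lowest called fold changes with a mean of at least 5 CPM, complete separation of the genotypes and a name that is not a clone, locus or model. It also names up to 2 risen and 2 fallen members per list, or the 2 with the highest mean CPM where none passed, the 12 called ligands with the smallest p, and the 3 called genes nearest to clcn7. Of the genes this rule names, 1 is not reported here. Names made of a clone accession were taken as clones under the same rule, a reading applied after their values were seen. krt91, col1a2, col1a1b and the genes that open the other observations were named after their values were seen.

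Chromosomes came from a table of the GRCz12tu assembly, which differs from the authors' assembly, so no coordinates are given. Symbols or synonyms placed 17185 of the tested genes (84.1%). The share of called genes on the clcn7 chromosome, without clcn7, was compared with all other chromosomes by a two-sided Fisher's exact test. Alternatives were RLE and upper-quartile factors, no filter and a stricter filter (1 CPM in 3 libraries and a mean count of 10), DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, glmTreat against a fold of 1.5, and leaving out each library. For the chromosome, an unadjusted p under 0.01 and the 10 Mb window were also used. Counts of list members without a library are given where at least 5 members moved in a direction and the count moved by over 1.5 times. Restored mitochondrial reads, library size alone and the ligand list with every gene that shares a prefix were added after the data were seen. No 2 replicates had counts alike enough to be a repeat deposit of the same library (chi-square per degree of freedom of 34.0 or more).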

Results

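Gene expression was measured by bulk RNA sequencing of dsRed-positive cells sorted from the skeletal tissue of zebrafish at 10 weeks post fertilization. The fish carried a ctsk:dsRed reporter, in which the promoter of cathepsin K, a collagen-degrading protease of osteoclasts, drives a red fluorescent protein. Mutants homozygous for a clcn7 allele were compared with WT siblings, with 3 libraries per genotype and 6 in all. Each library held cells of 2 fish, with 5000 sorted cells from each fish. clcn7 encodes a lysosomal chloride/proton exchanger that osteoclasts need to acidify the resorption space, and the series title gives the purpose as a search for bone-forming factors made by osteoclasts that do not resorb. The WT libraries held 26399790, 26951306 and 24518036 read counts over genes, and the mutant libraries 22739782, 26856895 and 25829347. Mitochondrial genes stand at 0 in the deposited counts. Among all other genes, the most abundant in WT libraries were the epidermal keratin gene krt91 and the bone collagen genes col1a2 and col1a1b. krt91 stood at 25979.7 ± 2269 CPM in WT and 12964 ± 2752 CPM in mutants (SD, n = 3), and col1a2 at 24383 ± 4824 CPM in WT and 17045 ± 3695 CPM in mutants. col1a1b stood at 23439.5 ± 4543 CPM in WT and 16363 ± 3502 CPM in mutants. ctsk itself stood at 666 ± 310.2 CPM in WT and 1194 ± 121 CPM in mutants.

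The clcn7 transcript was detected in all 6 libraries and did not pass the test between genotypes. It measured 34, 30.5 and 26.1 CPM in WT replicates 1, 2 and 3 and 39.1, 28 and 37.8 CPM in mutant replicates 1, 2 and 3, a log2 fold change of 0.21 ± 0.18 (SE; edgeR adjusted p = 0.482). The labels do not describe the allele, so this level does not check the genotype labels. ostm1, which encodes the beta subunit of the exchanger, rose from 24.9, 17.8 and 17 CPM in the WT libraries to 56.8, 37 and 52.3 CPM in the mutant libraries (log2 fold change 1.29 ± 0.22, edgeR adjusted p = 0.0093).

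Most of the 7 osteoclast genes chosen in advance did not pass the edgeR test with all 6 libraries. ctsk had a log2 fold change of 0.84 ± 0.30 (edgeR adjusted p = 0.102), and its 3 mutant libraries lay above its 3 WT libraries. Alternatives in which ctsk passed included DESeq2 (adjusted p = 0.0283), limma-voom (adjusted p = 0.024) and the fit without WT replicate 1 (log2 fold change 1.33, edgeR adjusted p = 0.00515). Over all alternatives run its adjusted p lay between 0.00515 and 0.457. The tartrate-resistant acid phosphatase genes acp5a (0.42 ± 0.47) and acp5b (1.78 ± 0.89), the RANK receptor gene tnfrsf11a (-0.33 ± 0.20) and the gelatinase gene mmp9 (-0.04 ± 0.22) did not pass either, with edgeR adjusted p of 0.598, 0.223, 0.309 and 0.922. csf1ra, a receptor for macrophage colony-stimulating factor, rose by 1.75 ± 0.48 on the log2 scale (edgeR adjusted p = 0.0493), and nfatc1, a transcription factor of osteoclast differentiation, fell, with a log2 fold change of -0.65 ± 0.17 (edgeR adjusted p = 0.0415). acp5a passed without WT replicate 1 (log2 fold change 1.21, edgeR adjusted p = 0.0455) and in no other alternative run, with adjusted p between 0.0455 and 1. WT replicate 1 stood apart from the other WT libraries for ctsk, acp5a and csf1ra, at 1024 CPM of ctsk against 464 and 512, 1237 CPM of acp5a against 378 and 432, and 36.6 CPM of csf1ra against 11 and 11.8. Over all alternatives run, the adjusted p lay between 0.000955 and 0.151 for csf1ra and between 0.0078 and 0.618 for nfatc1, the highest for nfatc1 with glmTreat. Calls that leaving out 1 library ended in edgeR were those of csf1ra (adjusted p = 0.151 without WT replicate 3, call kept in 1 of 6 fits) and nfatc1 (adjusted p = 0.17 without WT replicate 2, call kept in 2 of 6 fits). Calls that another scaling or filter, or limma-voom, ended were those of csf1ra (adjusted p = 0.0519 with RLE factors and adjusted p = 0.0508 with upper-quartile factors) and nfatc1 (adjusted p = 0.0888 with library size alone). Tested against a fold of 1.5 with glmTreat, calls were lost for csf1ra (adjusted p = 0.138) and nfatc1 (adjusted p = 0.618). acp5b had a log2 fold change of 2.64 without WT replicate 1 and 1.16 without mutant replicate 3. csf1ra had a log2 fold change of 2.59 without WT replicate 1.

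**Figure D1:**
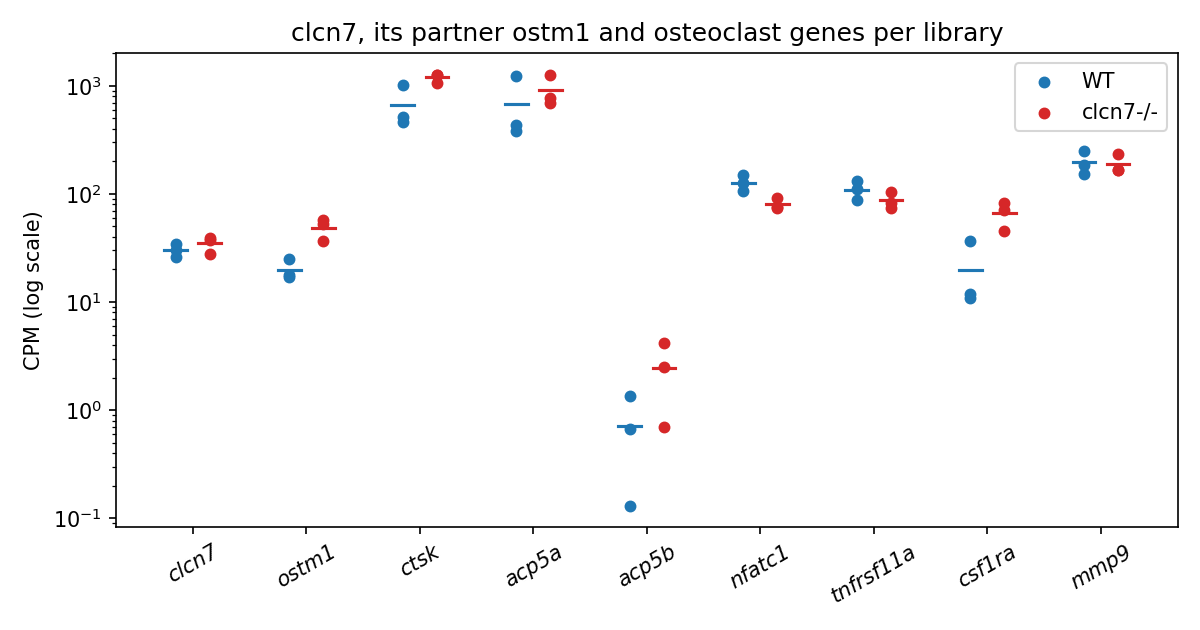
CPM (log scale) of clcn7, ostm1 and 7 osteoclast genes in each of the 3 WT (blue) and 3 clcn7-/- (red) libraries, with a horizontal line at each genotype's mean. The 3 mutant libraries lie above the 3 WT libraries for ostm1, ctsk and csf1ra and below them for nfatc1, and the genotypes overlap for clcn7.

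Across the transcriptome, 3012 of 20438 tested genes differed between genotypes, 2025 higher and 987 lower in mutants (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The chemokine gene cxcl19 had the highest fitted change that met the naming rule, from 6.75 ± 1.12 to 564 ± 293 CPM (SD, n = 3; log2 fold change 6.38 ± 0.49, edgeR adjusted p = 0.000663). The next were gda, which encodes guanine deaminase (5.66 ± 0.59), tmem163a (5.20 ± 0.44) and the granulin gene grn1 (5.05 ± 0.65). After them came the glycoprotein gene gpnmb (5.03 ± 0.91), the sugar transporter gene slc2a6 (4.86 ± 0.35) and the immune adaptor gene card9 (4.79 ± 0.33). The last of the 8 was acod1, whose product makes itaconate in activated macrophages (4.70 ± 0.22). Lowest were the organic anion transporter genes slco1f1 (-6.91 ± 1.63) and slco1f4 (-4.68 ± 1.09), close relatives whose reads the counting could split. They were followed by apnl (-3.70 ± 0.30), the epithelial collagen gene col17a1a (-3.22 ± 0.73), the fibrinogen gene fga (-3.05 ± 0.78), calb2b, pvalb8 (-2.60 ± 0.72) and the claudin gene cldn7a (-2.42 ± 0.47). The calcium-binding protein gene calb2b went from 13.2 ± 0.786 to 1.67 ± 1.49 CPM. WT replicate 1 held only 0.433 CPM of slco1f1 against 27.5 and 18.3 in the other WT libraries, and the mutant libraries held 0, 0.351 and 0 CPM. The split of calls moved with the scaling, to 1787 higher and 1675 lower with upper-quartile factors and 2626 and 564 with library size alone. The median log2 fold change of all tested genes was -0.05 with TMM, -0.16 with upper-quartile factors and 0.10 with library size alone. The number of called genes was 1548 without WT replicate 2, 1356 without WT replicate 3, 1867 without mutant replicate 1 and 1894 without mutant replicate 3. The higher genes numbered 1240 without WT replicate 2, 1157 without WT replicate 3 and 1327 without mutant replicate 1. The lower genes numbered 647 without WT replicate 1, 308 without WT replicate 2, 199 without WT replicate 3, 540 without mutant replicate 1 and 478 without mutant replicate 3. The edgeR calls lost without 1 library were those of slco1f1 (adjusted p = 0.0916 without WT replicate 2, call kept in 1 of 6 fits), slco1f4 (adjusted p = 0.0904 without mutant replicate 1, call kept in 1 of 6 fits), col17a1a (adjusted p = 0.0791 without WT replicate 1, call kept in 1 of 6 fits), fga (adjusted p = 0.143 without WT replicate 3, call kept in 2 of 6 fits), pvalb8 (adjusted p = 0.142 without WT replicate 2, call kept in 1 of 6 fits) and cldn7a (adjusted p = 0.0556 without mutant replicate 1, call kept in 4 of 6 fits). With another scaling or filter, or with limma-voom, calls were lost for slco1f1 (adjusted p = 0.412 with limma-voom), slco1f4 (adjusted p = 0.313 with limma-voom), fga (adjusted p = 0.0697 with limma-voom) and pvalb8 (adjusted p = 0.0503 with RLE factors, adjusted p = 0.133 with limma-voom and adjusted p = 0.0587 with library size alone). Calls that glmTreat against a fold of 1.5 ended were those of slco1f1 (adjusted p = 0.0525), slco1f4 (adjusted p = 0.0517), col17a1a (adjusted p = 0.0508), fga (adjusted p = 0.0814) and pvalb8 (adjusted p = 0.109). gpnmb had a log2 fold change of 5.83 with limma-voom and 6.24 without WT replicate 2. slco1f1 had a log2 fold change of -7.58 with limma-voom, -6.16 without WT replicate 2, -11.59 without mutant replicate 2 and -6.31 without mutant replicate 3. slco1f4 had a log2 fold change of -3.79 without WT replicate 2. col17a1a had a log2 fold change of -2.56 without WT replicate 1 and -4.37 without mutant replicate 2. fga had a log2 fold change of -2.13 without WT replicate 3 and -4.08 without mutant replicate 3. pvalb8 had a log2 fold change of -1.50 without WT replicate 2. cldn7a had a log2 fold change of -1.68 without WT replicate 2.

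The first lists cover the lysosome and autophagy. In the lysosomal list, of 64 measured members 48 rose and 1 fell, and adjusted over the list alone 49 rose and 2 fell. The median log2 fold change was 1.34, and camera gave adjusted p = 2.4e-29 with the preset and adjusted p = 0.212 with an estimated correlation. The asparaginyl endopeptidase gene lgmn went from 379.6 ± 81.5 to 5086 ± 1295 CPM (3.74 ± 0.27) and the cathepsin S gene ctss2.1 from 39.8 ± 8.93 to 313 ± 82.6 CPM (2.97 ± 0.26), while lamp1b fell by 0.60 on the log2 scale. For the V-ATPase proton pump, of 25 measured members 17 rose, and adjusted over the list alone 17 rose and 1 fell. Their median log2 fold change was 1.64, and camera gave adjusted p = 1.86e-12 with the preset and adjusted p = 0.245 with an estimated correlation. Its risers included atp6v1e1b (2.01 ± 0.24) and atp6v1f (1.77 ± 0.21). In the autophagy and TFEB/MiT list, of 38 measured members 9 rose and 2 fell, and adjusted over the list alone 14 rose and 2 fell. With a median log2 fold change of 0.29, the list had a camera adjusted p = 0.00439 with the preset and adjusted p = 0.36 with an estimated correlation. The MiT transcription factor genes tfec (3.83 ± 0.23) and mitfb (3.24 ± 0.37) rose, and map1lc3a (-0.63 ± 0.14) and rragd (-1.40 ± 0.38) fell. Among CLC channels and transporters, of 9 measured members 1 rose, and adjusted over the list alone 1 rose. Members had a median log2 fold change of 0.24 and a camera adjusted p = 0.512 with the preset and adjusted p = 0.566 with an estimated correlation. The riser was ostm1. The medians of macrophage and neutrophil markers were 2.26 and 2.64. Leaving out 1 library ended the edgeR call of lamp1b (adjusted p = 0.0958 without WT replicate 3, call kept in 2 of 6 fits), map1lc3a (adjusted p = 0.114 without WT replicate 3, call kept in 2 of 6 fits) and rragd (adjusted p = 0.191 without WT replicate 3, call kept in 0 of 6 fits). Another scaling or filter, or limma-voom, ended the call of lamp1b (adjusted p = 0.059 with library size alone), map1lc3a (adjusted p = 0.0545 with library size alone) and rragd (adjusted p = 0.0673 with no low-count filter and adjusted p = 0.0668 with library size alone). glmTreat against a fold of 1.5 ended the call of lamp1b (adjusted p = 0.733), map1lc3a (adjusted p = 0.638) and rragd (adjusted p = 0.167).

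The osteoclast list had a smaller median than the lysosomal list. Here of 37 measured members 12 rose and 1 fell, and adjusted over the list alone 14 rose and 2 fell. At a median log2 fold change of 0.37, camera gave adjusted p = 5.53e-05 with the preset and adjusted p = 0.353 with an estimated correlation. Without WT replicate 1, 16 members rose and the median was 0.94. The risers with the smallest p were tfec and the myeloid transcription factor gene spi1a (2.76 ± 0.29). Metalloproteinases and their inhibitors went both ways: of 30 measured members 5 rose and 4 fell, and adjusted over the list alone 5 rose and 5 fell. camera gave adjusted p = 0.565 with the preset and adjusted p = 0.781 with an estimated correlation, at a median log2 fold change of -0.22. Their mean was 0.12, opposite in sign to the median, and camera's direction was up. adam8a (2.40 ± 0.13) and mmp25b (4.07 ± 0.28) rose, and timp4.1 (-1.27 ± 0.25) and mmp23bb (-0.95 ± 0.22) fell. The 12 osteoclast risers became 7 without WT replicates 2 or 3 or mutant replicates 1 or 3. Calls that leaving out 1 library ended in edgeR were those of mmp23bb (adjusted p = 0.103 without WT replicate 3, call kept in 2 of 6 fits). Tested against a fold of 1.5 with glmTreat, calls were lost for timp4.1 (adjusted p = 0.068) and mmp23bb (adjusted p = 0.197).

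Secreted factors were the class named by the purpose of the series. For the osteoclast-derived coupling factors, of 56 measured members 2 rose and 13 fell, and adjusted over the list alone 2 rose and 14 fell. The list's median log2 fold change was -0.46, with a camera adjusted p = 0.000356 with the preset and adjusted p = 0.333 with an estimated correlation. tgfb1b went from 12 ± 0.722 to 37.5 ± 2.69 CPM (1.65 ± 0.14) and the platelet-derived growth factor gene pdgfba from 19.8 ± 2.3 to 53.3 ± 16.8 CPM (1.43 ± 0.24). The fallen members included vegfaa (-1.39 ± 0.16) and bmp4 (-1.06 ± 0.18), which encode angiogenic and bone morphogenetic ligands. In the wider ligand list, of 309 measured members 26 rose and 44 fell, and adjusted over the list alone 28 rose and 68 fell. The median log2 fold change was -0.46, and camera gave adjusted p = 0.0054 with the preset and adjusted p = 0.353 with an estimated correlation. Of the 12 called members of both lists with the smallest p, 11 rose. They included csf3a (4.35 ± 0.19) and csf3b (3.68 ± 0.32), which encode granulocyte colony-stimulating factors, the galectin gene lgals9l1 (4.65 ± 0.36) and the chemokine genes ccl34a.4 (4.11 ± 0.39), ccl35.1 (2.95 ± 0.34) and ccl38.1 (2.01 ± 0.24). The others were cxcl19, tgfb1b, the tumour necrosis factor gene tnfb (2.95 ± 0.29), angpt2a (4.66 ± 0.50) and il16 (1.29 ± 0.14). The faller was vegfaa, and the antagonist gene nog2 (-1.03 ± 0.16) also fell. Beside these ligands, the median log2 fold change was 2.64 for neutrophil and 2.26 for macrophage markers, and -0.73, -0.56 and -1.27 for osteoblast, fibroblast and keratinocyte markers. The 13 coupling factor fallen members became 2 without WT replicate 3 or mutant replicate 3, 3 without WT replicate 2 and 6 without WT replicate 1 or mutant replicate 1. The 44 ligand fallen members became 8 without WT replicate 3, 10 without WT replicate 2, 16 without mutant replicate 3 and 26 without WT replicate 1. Calls that glmTreat against a fold of 1.5 ended were those of bmp4 (adjusted p = 0.0647) and nog2 (adjusted p = 0.0538).

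**Figure D2:**
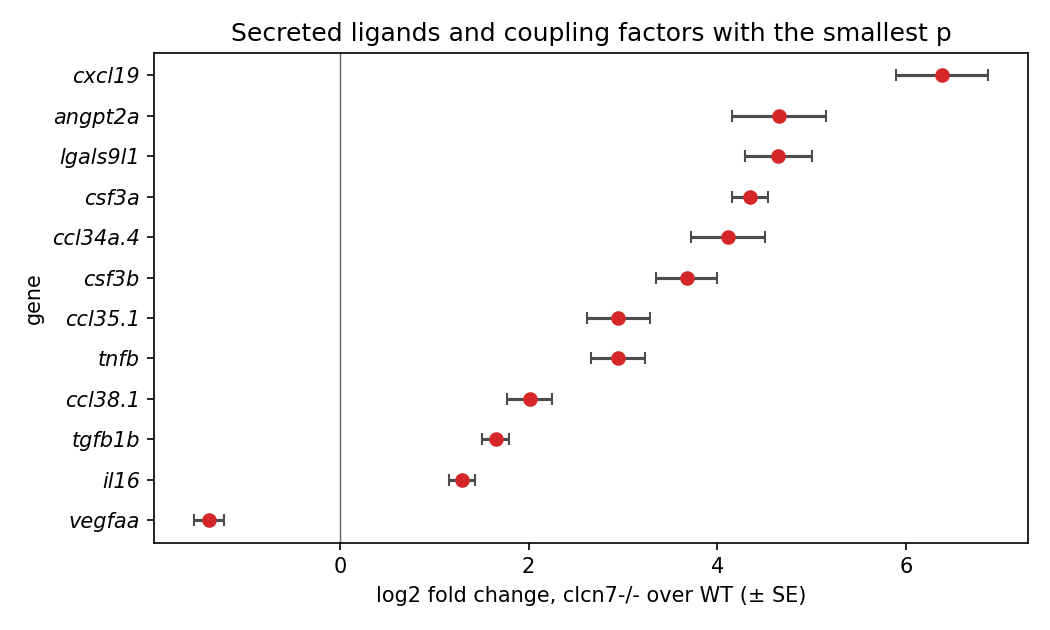
Log2 fold change (clcn7-/- over WT, 3 libraries each) of the 12 secreted ligand and coupling factor genes with the smallest p. Points are fitted values and bars are SE, and 11 of the 12 lie above 0, from il16 at 1.29 to cxcl19 at 6.38.

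The next lists hold markers of blood and immune cells. For neutrophils, of 19 measured members 17 rose, and adjusted over the list alone 18 rose and 1 fell. Their median log2 fold change was 2.64, and camera gave adjusted p = 5.47e-43 with the preset and adjusted p = 0.046 with an estimated correlation. The chemotaxin gene lect2l (3.03 ± 0.16) and adam8a were among the risers. For macrophages, of 29 measured members 23 rose and 1 fell, and adjusted over the list alone 24 rose and 1 fell. With a median log2 fold change of 2.26, the list had a camera adjusted p = 2.03e-23 with the preset and adjusted p = 0.245 with an estimated correlation. il10ra (3.68 ± 0.30) and slc7a7 (3.60 ± 0.30) rose and the apolipoprotein gene apoeb fell by 0.81 on the log2 scale. For erythroid cells, of 20 measured members 17 rose, and adjusted over the list alone 20 rose. Members had a median log2 fold change of 2.26 and a camera adjusted p = 7.04e-15 with the preset and adjusted p = 0.245 with an estimated correlation. The risers included hemgn (2.50 ± 0.33) and klf1 (2.65 ± 0.35), and reads of the near-identical globin genes of this list could be split. For lymphocytes, of 28 measured members 6 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell. At a median log2 fold change of 0.93, camera gave adjusted p = 0.00439 with the preset and adjusted p = 0.359 with an estimated correlation. tagapa (1.78 ± 0.20) and ikzf1 (2.39 ± 0.32) rose and gata3 (-1.44 ± 0.20) fell. For thrombocytes, of 12 measured members 2 rose, and adjusted over the list alone 4 rose and 1 fell. camera gave adjusted p = 0.00362 with the preset and adjusted p = 0.212 with an estimated correlation, at a median log2 fold change of 0.87. The risers were selp (3.61 ± 0.25) and mrc1b (3.07 ± 0.26). The 17 erythroid risers became 11 without WT replicates 2 or 3. The 6 lymphocyte risers became 3 without WT replicate 3 or mutant replicates 1 or 3. The thrombocyte median became 1.56 without WT replicate 1. glmTreat against a fold of 1.5 ended the call of apoeb (adjusted p = 0.185).

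Inflammation and immune response were covered by 3 lists. In the same libraries neutrophil and macrophage markers had median log2 fold changes of 2.64 and 2.26. In the list of inflammatory cytokines and NF-kB feedback, of 44 measured members 18 rose and 2 fell, and adjusted over the list alone 20 rose and 4 fell. The list's median log2 fold change was 0.80, with a camera adjusted p = 1.6e-08 with the preset and adjusted p = 0.212 with an estimated correlation. acod1 and tnfaip2b (3.73 ± 0.34) rose, and csf1a (-0.94 ± 0.25) and the cytokine feedback gene socs3a (-0.58 ± 0.16) fell. For antigen presentation, of 17 measured members 6 rose, and adjusted over the list alone 8 rose. The median log2 fold change was 0.59, and camera gave adjusted p = 0.000356 with the preset and adjusted p = 0.36 with an estimated correlation. ctss2.1 and its near copy ctss2.2 (2.99 ± 0.39) led the risers. In the interferon list, of 27 measured members 3 rose, and adjusted over the list alone 1 rose. Their median log2 fold change was 0.06, and camera gave adjusted p = 0.677 with the preset and adjusted p = 0.918 with an estimated correlation. Its named members are the immunoproteasome genes psmb12 (1.00 ± 0.20) and psmb8a (0.84 ± 0.22). The interferon median changed sign with upper-quartile factors (-0.05) and without mutant replicate 1 (-0.08). The 18 inflammatory risers became 11 without WT replicate 2. The 6 antigen presentation risers became 2 without WT replicates 2 or 3 or mutant replicates 1 or 3. The edgeR calls lost without 1 library were those of csf1a (adjusted p = 0.149 without WT replicate 2, call kept in 0 of 6 fits), socs3a (adjusted p = 0.208 without WT replicate 3, call kept in 0 of 6 fits), psmb12 (adjusted p = 0.0572 without WT replicate 3, call kept in 4 of 6 fits) and psmb8a (adjusted p = 0.126 without WT replicate 3, call kept in 2 of 6 fits). Calls that another scaling or filter, or limma-voom, ended were those of csf1a (adjusted p = 0.0594 with library size alone), socs3a (adjusted p = 0.0683 with no low-count filter and adjusted p = 0.0998 with library size alone) and psmb8a (adjusted p = 0.0525 with upper-quartile factors). Tested against a fold of 1.5 with glmTreat, calls were lost for csf1a (adjusted p = 0.248), socs3a (adjusted p = 0.801), psmb12 (adjusted p = 0.113) and psmb8a (adjusted p = 0.319).

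Markers of epidermal and skeletal cells stand here beside genes of cholesterol synthesis. For keratinocytes and epithelium, of 31 measured members 16 fell, and adjusted over the list alone 21 fell. With a median log2 fold change of -1.27, the list had a camera adjusted p = 3.59e-12 with the preset and adjusted p = 0.212 with an estimated correlation. These markers held 6.68% ± 0.234 of gene counts in WT and 3.64% ± 0.628 in mutants (SD, n = 3). icn2 (-1.97 ± 0.30) and the claudin gene cldn1 (-1.71 ± 0.30) fell. For osteoblasts and bone matrix, of 28 measured members 9 fell, and adjusted over the list alone 13 fell. Members had a median log2 fold change of -0.73 and a camera adjusted p = 8.91e-08 with the preset and adjusted p = 0.333 with an estimated correlation. The alkaline phosphatase gene alpl (-0.96 ± 0.14) and the collagen gene col10a1a (-1.81 ± 0.30) fell. For fibroblasts and tenocytes, of 26 measured members 5 fell, and adjusted over the list alone 12 fell. At a median log2 fold change of -0.56, camera gave adjusted p = 4.54e-05 with the preset and adjusted p = 0.353 with an estimated correlation. twist2 (-1.18 ± 0.20) and mfap5 (-0.90 ± 0.17) fell. For chondrocytes, of 23 measured members 2 fell, and no member passed when adjusted over the list alone. camera gave adjusted p = 0.0192 with the preset and adjusted p = 0.443 with an estimated correlation, at a median log2 fold change of -0.42. sox9b (-1.52 ± 0.34) and col11a2 (-1.23 ± 0.32) fell. In the cholesterol synthesis and uptake list, of 26 measured members 6 fell, and adjusted over the list alone 20 fell. The list's median log2 fold change was -1.60, with a camera adjusted p = 4.03e-10 with the preset and adjusted p = 0.353 with an estimated correlation. acat2, a fallen member, went from 109.9 ± 36.2 to 27.5 ± 17 CPM. The 16 keratinocyte fallen members became 3 without WT replicate 3, 7 without mutant replicate 1 and 9 without WT replicate 2 or mutant replicate 3. The 9 osteoblast fallen members became 2 without WT replicate 2 or mutant replicate 3 and 5 without WT replicates 1 or 3 or mutant replicate 1. The 5 fibroblast fallen members became 1 without WT replicates 2 or 3 and 2 without mutant replicates 2 or 3. The 6 cholesterol fallen members became 1 without WT replicate 3 or mutant replicate 2, 2 without WT replicate 1, 3 without WT replicate 2 and 18 without mutant replicate 1. The cholesterol median became -2.39 without mutant replicate 1. Leaving out 1 library ended the edgeR call of mfap5 (adjusted p = 0.0645 without WT replicate 3, call kept in 4 of 6 fits), sox9b (adjusted p = 0.107 without WT replicate 3, call kept in 2 of 6 fits), col11a2 (adjusted p = 0.143 without WT replicate 2, call kept in 1 of 6 fits) and acat2 (adjusted p = 0.0832 without WT replicate 3, call kept in 4 of 6 fits). camera no longer called the chondrocyte list without WT replicate 2 (adjusted p = 0.0871) and without mutant replicate 3 (adjusted p = 0.0737). With another scaling or filter, or with limma-voom, calls were lost for col11a2 (adjusted p = 0.091 with limma-voom and adjusted p = 0.0577 with library size alone). Calls that glmTreat against a fold of 1.5 ended were those of alpl (adjusted p = 0.0577), mfap5 (adjusted p = 0.158), sox9b (adjusted p = 0.0826), col11a2 (adjusted p = 0.161) and acat2 (adjusted p = 0.0597).

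Other cell types gave mixed results. For endothelium, of 28 measured members 8 rose and 1 fell, and adjusted over the list alone 12 rose and 1 fell. The median log2 fold change was 1.11, and camera gave adjusted p = 1.22e-06 with the preset and adjusted p = 0.36 with an estimated correlation. fli1b went from 10.1 ± 0.627 to 46.3 ± 7.33 CPM, flt4 (3.34 ± 0.38) rose and flt1 (-1.41 ± 0.34) fell. For skeletal muscle, of 34 measured members 9 rose and 1 fell, and adjusted over the list alone 14 rose and 2 fell. Their median log2 fold change was 1.11, and camera gave adjusted p = 0.00362 with the preset and adjusted p = 0.443 with an estimated correlation. myl1 stood at 0.406 ± 0.0611 CPM in WT and 3.83 ± 1.8 CPM in mutants and pvalb2 at 0.765 ± 0.362 CPM in WT and 7.32 ± 4.98 CPM in mutants, and tpm2 (-0.82 ± 0.15) fell. Among pigment cell markers, of 21 measured members 3 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell. With a median log2 fold change of -0.45, the list had a camera adjusted p = 0.625 with the preset and adjusted p = 0.751 with an estimated correlation. Their mean was 0.20, opposite in sign to the median, and camera's direction was up. tfec and gpnmb, which other lists also hold, rose and impdh1b (-0.64 ± 0.13) fell. Among nerve and glial markers, of 25 measured members 1 rose, and adjusted over the list alone 1 rose. Members had a median log2 fold change of -0.11 and a camera adjusted p = 0.825 with the preset and adjusted p = 0.919 with an estimated correlation. Their mean was 0.04, opposite in sign to the median, and camera's direction was down. The riser was plp1b (2.08 ± 0.45). The endothelial median became 0.52 without mutant replicate 2. The 9 muscle risers became 1 without WT replicate 3, 3 without WT replicate 2, 4 without mutant replicate 1 and 5 without WT replicate 1 or mutant replicate 3. The muscle median became 1.84 without WT replicate 1. Calls that leaving out 1 library ended in edgeR were those of flt1 (adjusted p = 0.128 without WT replicate 2, call kept in 1 of 6 fits), pvalb2 (adjusted p = 0.0505 without WT replicate 3, call kept in 5 of 6 fits), tpm2 (adjusted p = 0.0552 without WT replicate 3, call kept in 5 of 6 fits), impdh1b (adjusted p = 0.0841 without WT replicate 3, call kept in 3 of 6 fits) and plp1b (adjusted p = 0.0872 without WT replicate 3, call kept in 4 of 6 fits). camera no longer called the muscle list without mutant replicate 3 (adjusted p = 0.0657). glmTreat against a fold of 1.5 ended the call of flt1 (adjusted p = 0.115), tpm2 (adjusted p = 0.203), impdh1b (adjusted p = 0.596) and plp1b (adjusted p = 0.0548). plp1b had a log2 fold change of 1.46 without mutant replicate 3. That of pvalb2 was 3.25 with all libraries and 2.54 without mutant replicate 1.

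Growth and metabolism were covered by 4 of the lists below. For the cell cycle, of 43 measured members 30 rose, and adjusted over the list alone 33 rose. At a median log2 fold change of 1.45, camera gave adjusted p = 1.3e-16 with the preset and adjusted p = 0.251 with an estimated correlation. plk1 (1.85 ± 0.20) and cdc20 (2.29 ± 0.31) rose. For the unfolded protein response, of 32 measured members 11 rose, and adjusted over the list alone 12 rose. camera gave adjusted p = 0.000857 with the preset and adjusted p = 0.321 with an estimated correlation, at a median log2 fold change of 0.40. calr3b (1.39 ± 0.18) and sdf2l1 (0.98 ± 0.16) rose. For glycolysis, of 32 measured members 8 rose, and adjusted over the list alone 10 rose. The list's median log2 fold change was 0.53, with a camera adjusted p = 0.000156 with the preset and adjusted p = 0.353 with an estimated correlation. pfkpa (1.18 ± 0.13) and the hexokinase gene hk2 (1.36 ± 0.16) rose. For cytosolic ribosomal proteins, of 81 measured members 39 fell, and adjusted over the list alone 1 rose and 76 fell. The median log2 fold change was -0.54, and camera gave adjusted p = 7.04e-15 with the preset and adjusted p = 0.381 with an estimated correlation. rps26 (-0.79 ± 0.17) and rps27.1 (-0.69 ± 0.15) fell. In the same libraries the medians of erythroid, macrophage and neutrophil markers were 2.26, 2.26 and 2.64, and those of osteoblast, fibroblast and keratinocyte markers -0.73, -0.56 and -1.27. The 30 cell cycle risers became 18 without mutant replicate 1. The 11 unfolded protein response risers became 3 without WT replicate 3 and 5 without WT replicate 2 or mutant replicate 1. The 8 glycolysis risers became 5 without WT replicate 2 or mutant replicates 1 or 3. The 39 ribosomal protein fallen members became 0 without WT replicates 2 or 3 or mutant replicates 1 or 3 (41 to 71 at an unadjusted p under 0.05 in edgeR) and 10 without mutant replicate 2. The edgeR calls lost without 1 library were those of rps26 (adjusted p = 0.099 without WT replicate 3, call kept in 2 of 6 fits) and rps27.1 (adjusted p = 0.107 without WT replicate 3, call kept in 2 of 6 fits). Tested against a fold of 1.5 with glmTreat, calls were lost for sdf2l1 (adjusted p = 0.08), rps26 (adjusted p = 0.3) and rps27.1 (adjusted p = 0.492).

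With its preset correlation and all 6 libraries, camera did not call the next 3 lists. For nuclear oxidative phosphorylation, of 99 measured members 10 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell. Their median log2 fold change was 0.16, and camera gave adjusted p = 0.0553 with the preset and adjusted p = 0.781 with an estimated correlation. ndufa4 (2.19 ± 0.30) and cox6b1 (1.35 ± 0.19) rose and sdhda (-1.75 ± 0.30) fell. For iron, heme and oxidative stress, of 35 measured members 7 rose and 3 fell, and adjusted over the list alone 9 rose and 5 fell. With a median log2 fold change of 0.08, the list had a camera adjusted p = 0.14 with the preset and adjusted p = 0.409 with an estimated correlation. gpx1a (1.91 ± 0.14) and slc7a11 (3.46 ± 0.32) rose, and gpx4a (-1.09 ± 0.18) and sod1 (-0.69 ± 0.14) fell. For dissociation stress and immediate-early genes, of 43 measured members 5 rose and 5 fell, and adjusted over the list alone 7 rose and 5 fell. Members had a median log2 fold change of -0.15 and a camera adjusted p = 0.565 with the preset and adjusted p = 0.918 with an estimated correlation. nr4a1 (1.21 ± 0.15) rose and cebpb went from 751 ± 159 to 1856 ± 166 CPM, while klf2a (-0.97 ± 0.22) and fosab (-0.78 ± 0.18) fell. The median of the iron list changed sign with upper-quartile factors, and that of the stress list with library size alone. Mitochondrially encoded genes stand at 0 in the deposited counts of all 6 libraries. In the authors' deposited table the smallest adjusted p of a mitochondrial gene, from DESeq2, was 0.28. The 10 oxidative phosphorylation risers became 2 without WT replicate 2, 3 without WT replicate 3, 4 without WT replicate 1 or mutant replicates 1 or 3 and 6 without mutant replicate 2. The 5 dissociation stress risers became 3 without WT replicate 2. The 5 dissociation stress fallen members became 0 without WT replicates 2 or 3 (5 to 10 at an unadjusted p under 0.05 in edgeR), 1 without mutant replicates 1 or 3, 2 without WT replicate 1 and 3 without mutant replicate 2. Leaving out 1 library ended the edgeR call of sod1 (adjusted p = 0.0841 without WT replicate 3, call kept in 4 of 6 fits), klf2a (adjusted p = 0.0968 without WT replicate 3, call kept in 2 of 6 fits) and fosab (adjusted p = 0.13 without WT replicate 3, call kept in 2 of 6 fits). camera called the oxidative phosphorylation list with RLE factors (adjusted p = 0.0456), without WT replicate 2 (adjusted p = 0.025), without WT replicate 3 (adjusted p = 0.0056), without mutant replicate 1 (adjusted p = 0.0321) and without mutant replicate 2 (adjusted p = 0.0275). camera called the iron list without WT replicate 3 (adjusted p = 0.0457). Another scaling or filter, or limma-voom, ended the call of fosab (adjusted p = 0.0525 with library size alone). Calls that glmTreat against a fold of 1.5 ended were those of gpx4a (adjusted p = 0.0535), sod1 (adjusted p = 0.453), klf2a (adjusted p = 0.165) and fosab (adjusted p = 0.343).

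**Figure D3:**
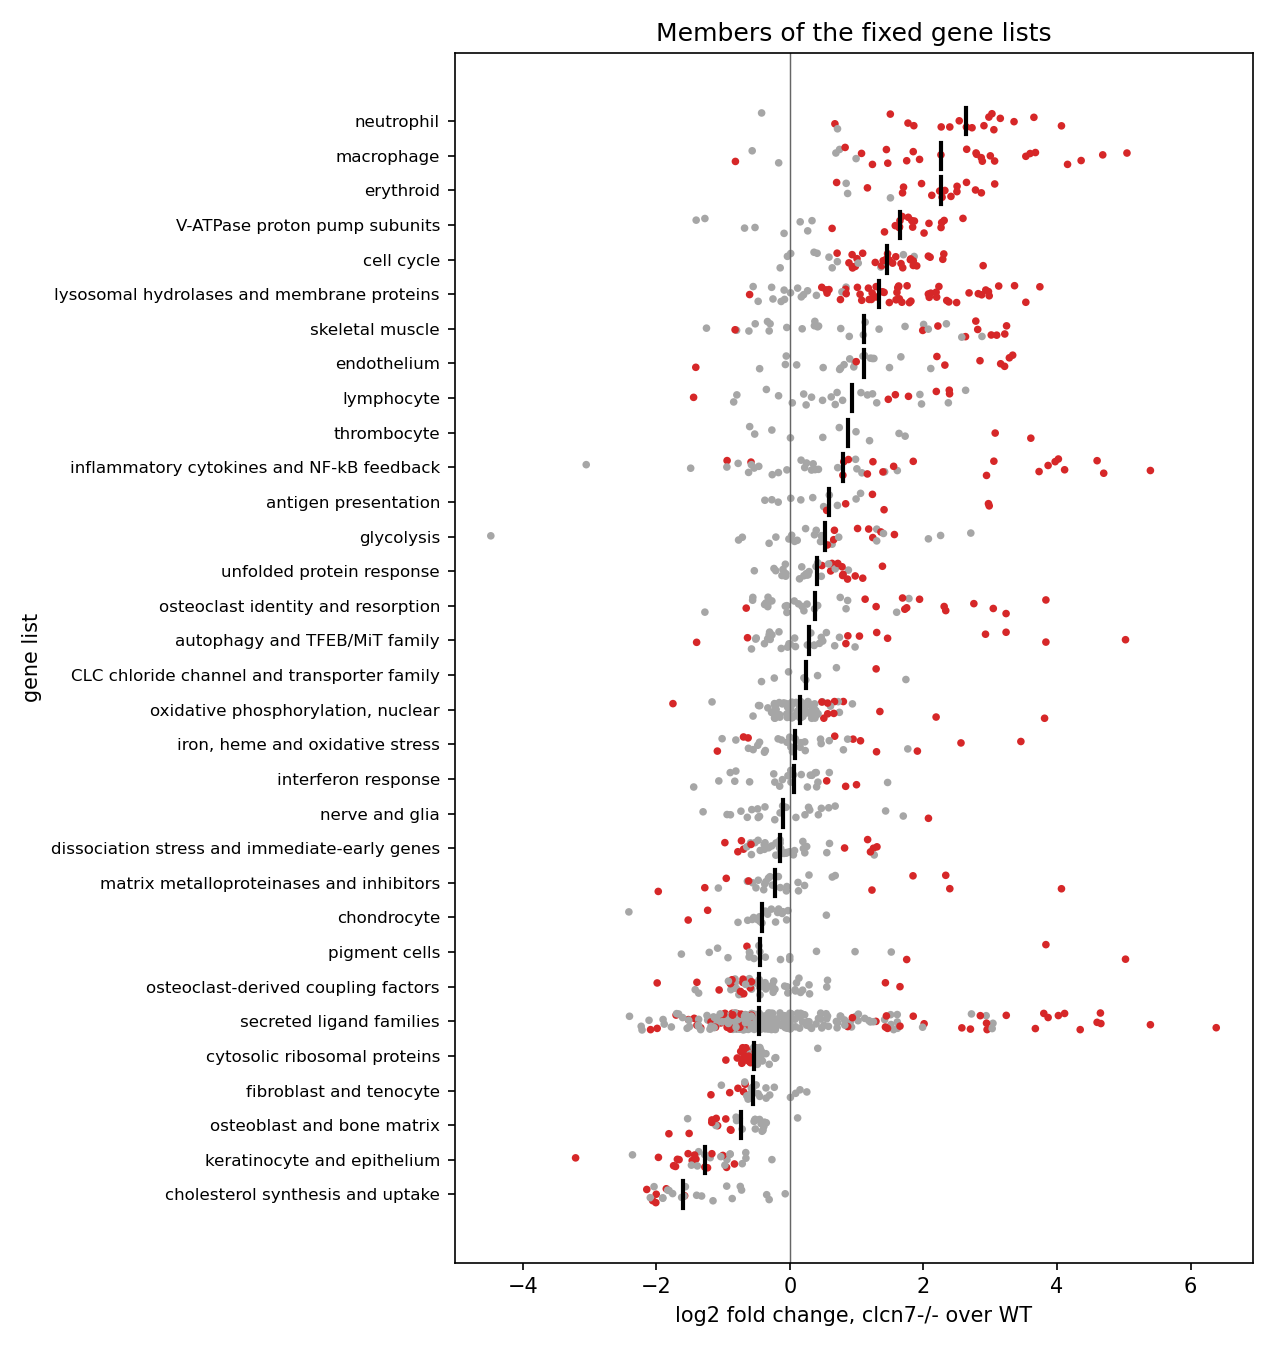
Log2 fold change (clcn7-/- over WT) of each measured member of the 32 gene lists with at least 5 tested genes, 1 point per gene, with red points at edgeR adjusted p under 0.05 and black bars at list medians. Medians run from -1.60 for cholesterol synthesis and uptake to 2.64 for neutrophil markers. With upper-quartile factors the medians of the iron and interferon lists lie below 0, and with library size alone those of the dissociation stress and nerve lists lie above 0.

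camera called 24 of the 32 lists with its preset correlation, 16 up and 8 down. With an estimated correlation it called 1, that of neutrophil markers. The self-contained test fry called 21 lists. Another split of the 6 libraries, which mixed the genotypes, also called 24 lists with the preset correlation. In the authors' deposited table, 4589 genes had an adjusted p from DESeq2 under 0.05, 2739 higher and 1850 lower in mutants. Of the 2960 genes called here that matched a gene with an adjusted p there, 2959 were also called there in the same direction. Both results come from the same libraries.

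Genes on the chromosome that carries clcn7 were called more often than genes on other chromosomes. There 170 of 906 tested genes were called (18.8%) against 2468 of 16278 elsewhere (15.2%). The odds ratio was 1.29, with a 95% interval of 1.08 to 1.54 (two-sided Fisher's exact test, p = 0.00445). Within 10 Mb of clcn7, 76 of 389 genes were called (odds ratio 1.35, Fisher's exact p = 0.0228). For called genes on the clcn7 chromosome, the odds ratio without mutant replicate 1 was 1.21 (Fisher's exact p = 0.0805). The 3 called genes nearest to clcn7 were arhgdig (1.38 ± 0.19), emp2 (-0.77 ± 0.12) and the cytokine feedback gene socs1a (1.55 ± 0.23). Genes are not independent replicates, so this test describes these genes and not the fish. glmTreat against a fold of 1.5 ended the call of emp2 (adjusted p = 0.217).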

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

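No gene called with all libraries changed sign under any alternative run. The count of called genes, 3012 (2025 higher and 987 lower), was 4563 with DESeq2 (1848 lower, the number of higher genes staying within 1.5 times), and 1191 with glmTreat against a fold of 1.5 (1057 higher and 134 lower), which by construction tests for larger changes. Upper-quartile factors gave 1675 lower genes and library size alone, an alternative added after seeing the data, 564; the cause was not tested beyond the shift of the median of all genes, -0.16 and 0.10 against -0.05. Leaving out 1 library, which leaves fewer samples, gave 1356 to 2527 called genes, 1157 to 1828 higher and 199 to 737 lower, with the lowest counts without WT replicate 3. Of 104 called named genes, 74 were called in each of the 6 fits without a library and 30 were lost in at least 1. glmTreat ended 36 of the 104 calls, library size alone 9, limma-voom 5, and RLE factors, upper-quartile factors and no low-count filter 2 each. Restoring the mitochondrial reads gave 3014 called genes, 3011 of them shared with the 3012. The list with every gene that shares a ligand prefix had 29 risers and 47 fallers among 332 tested genes. The count of called lists, 24, was 1 with an estimated correlation and 22 to 26 without a library. For called genes on the clcn7 chromosome, the odds ratio ran from 1.21 (Fisher's exact p = 0.0805) without clcn7-/- replicate 1 to 1.504 without clcn7-/- replicate 3, against 1.29 with all 6 libraries.

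Replicate numbers were not taken to pair the samples, since they are not said to mark a shared tank, day or sort. Deviations of same-numbered libraries from their genotype means correlated at 0.24, 0.03 and 0.16 across genes. Every library except WT replicate 2 correlated best with its own number, so an effect shared by replicate number is not excluded. With the replicate block, 3007 genes were called, 1940 higher and 1067 lower, with 24 called lists and an odds ratio of 1.26 for the chromosome. Of the 3012 genes, 2525 were also called with the block, so the near-equal totals hold different genes in part. The block moved the fallen members from 39 to 9 in the ribosomal list, 6 to 18 in the cholesterol list and 9 to 14 in the osteoblast list, and the endothelial risers from 8 to 13. Among named genes the block ended 3 calls, those of pvalb8 (edgeR adjusted p = 0.118), rragd (adjusted p = 0.0706) and socs3a (adjusted p = 0.0855), and ctsk passed (log2 fold change 0.93, adjusted p = 0.0454). slco1f4 kept its call, with a log2 fold change of -4.05 against -4.68. Leaving mitochondrial genes out of the counts was not run as a separate alternative, because they are 0 in the count files already. In the simulation with 200 changed genes, 54.3% of 4-fold changes and 13.7% of 2-fold changes were called, shares that depend on how many genes change.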

Other observations

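The tests in this part were chosen after the results were seen, except the comparison among chromosomes, which was written before its values were seen, and the permutation and Fisher's exact tests treat genes as independent, which they are not. Of the neutrophil markers, mpx went from 37.5 ± 12.1 to 385 ± 80.1 CPM, lyz from 7.82 ± 0.333 to 98.5 ± 29.1 CPM and npsn from 33.8 ± 6.79 to 254 ± 48 CPM (SD, n = 3). The most abundant neutrophil list member, s100a10b, stood at 3123 ± 498 CPM in WT and 2330.4 ± 215 CPM in mutants. The adult globin gene hbba1 went from 204 ± 66.2 to 891 ± 387 CPM. Scavenger receptor genes of the endothelial list, stab1 (3.29 ± 0.55), mrc1a (3.16 ± 0.56) and lyve1b (3.22 ± 0.48), were higher, while ramp2 was at 102 ± 47.8 CPM in WT and 98.4 ± 25.3 CPM in mutants. These genes were named after their values were seen.

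In the lysosomal, V-ATPase, macrophage and neutrophil lists 48 of 64, 17 of 25, 23 of 29 and 17 of 19 tested members rose, and camera gave adjusted p = 0.212, adjusted p = 0.245, adjusted p = 0.245 and adjusted p = 0.046 with an estimated correlation, so only the neutrophil list stayed called. A lower share of keratinocytes and stromal cells, with nothing else changed, would raise the markers of every other cell type alike. The median of 38 macrophage and neutrophil markers exceeded that of 68 lymphocyte, nerve and pigment markers by 2.62 on the log2 scale. A permutation test across genes gave p = 1e-05, the smallest that 100000 permutations can give. These lists were picked with their medians known, so that p-value is no support. Erythroid, endothelial, muscle and thrombocyte markers, not in the comparison, had medians of 2.26, 1.11, 1.11 and 0.87. Medians thus ran from -0.45 for pigment to 2.64 for neutrophil markers and were not alike. The lymphocyte, nerve and pigment lists had low means per library, 1.24 to 3.06 on the log2 scale. Endothelial and thrombocyte lists had means of 3.36 to 5.69, and their medians of 1.11 and 0.87 also lay below that of neutrophil markers. Erythroid markers, at 2.26, lay nearer to it. These differences were not tested, and as values they argue against dilution alone. More macrophages and neutrophils among the sorted mutant cells may account for part of the rise, which needs their markers to rise at least as much. Their markers exceeded the 88 lysosomal and V-ATPase genes that no marker list holds by 1.23 (permutation p = 1e-05). The 7 of 29 macrophage and 3 of 19 neutrophil markers that other lists also hold were left out. These medians were also known beforehand, so this p-value is no support either, and the explanation stays open. The dsRed gate would remove cells that lack the reporter. Yet keratinocyte and osteoblast markers held 6.68% and 8.01% of gene counts in WT and the osteoclast list 0.405%, so the gate does not decide against macrophages. These are shares of counts and do not measure shares of cells. The macrophage list held 0.283% ± 0.0478 of gene counts in WT and 0.948% ± 0.355 in mutants (SD, n = 3). Among its 23 risers, grn1 went from 27.8 ± 15.8 to 921 ± 527 CPM. cd74a stood at 894 ± 247 CPM in WT and 1778 ± 767 CPM in mutants, and apoeb was the 1 member that fell. Whether there were more osteoclasts stays open. The 7 osteoclast genes lay below the lysosomal genes by 1.07 in the median (difference -1.07, permutation p = 0.0883), a test on few genes that cannot decide. Of these, csf1ra is also a macrophage marker and acp5b stood at 0.713 CPM in WT and 2.48 CPM in mutants. The rest, ctsk, acp5a, mmp9, tnfrsf11a and nfatc1, had log2 fold changes of 0.84, 0.42, -0.04, -0.33 and -0.65. The ctsk promoter drives the reporter used for sorting, so the sort may set the level of ctsk in part. A change of the lysosomal genes within osteoclasts was not tested and cannot be separated from cell composition in bulk RNA.

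The share of called genes on the clcn7 chromosome may reflect a haplotype linked to the mutation, but inside the 10 Mb window the odds of a call were only 1.09 times those on the rest of that chromosome (Fisher's exact p = 0.607), which does not decide. Chromosomes also differed without reference to clcn7: 2 of 25, the clcn7 chromosome included, had an odds ratio as far from 1, the other being low at 0.744, and the clcn7 chromosome had the highest.

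Of the cholesterol list 6 of 26 tested members fell (1 to 18 without a library) and of the keratinocyte markers 16 of 31, and camera gave adjusted p = 0.353 and adjusted p = 0.212 with an estimated correlation. Fewer keratinocytes could lower cholesterol synthesis genes. The dsRed gate would remove cells that lack the reporter, yet keratinocyte markers held 6.68% of gene counts in WT. The medians differed by -0.33 on the log2 scale (cholesterol minus keratinocyte, permutation p = 0.0712), which does not decide. The size of this difference depends on single libraries. Without clcn7-/- replicate 1 the medians were -2.39 for cholesterol synthesis and -1.21 for keratinocyte markers. Without clcn7-/- replicate 2 they were -1.49 and -1.49, and neither difference was tested. In mutant replicates 1, 2 and 3 the list means on the log2 scale were 5.205, 5.978 and 5.241 for keratinocyte markers. Those of cholesterol synthesis were 5.84, 4.996 and 3.985. Replicates 1 and 3 were near equal in keratinocyte markers and far apart in cholesterol synthesis. Differences in cholesterol synthesis among the mutant libraries thus did not follow keratinocyte markers. This rests on 3 libraries, was not tested and does not address the fall between genotypes. Both lists were lower in mutants, so fewer keratinocytes as a cause of all or part of the fall stays open.

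The 6 libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. The real split called 3012 genes and the highest other split 0 (edgeR; between 202 and 989 genes at an unadjusted p under 0.05), with 1 split reaching the real count. For the lists, the real split called 24 and the highest other also 24, so 2 of the 10 splits called as many.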
